A study of Mus musculus with 3 samples.

How the data were processed

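Single-cell RNA sequencing libraries were made with the 10x Genomics 3 prime kit, version 2, from bone marrow of C57BL/6 mice after enrichment for cells bearing the receptor Kit. The labels give 3 libraries with 1 library in each group. They are a steady-state library (unchallenged), a library after 1 challenge with Escherichia coli labelled 24 h (challenged once), and a library after 2 challenges labelled 48 h (rechallenged). The source name label reads bone marrow neutrophil although the enrichment label names Kit, and the design text of the series mentions 2 samples and another treatment, so the sample labels were followed. From what moment the hours count, and whether animals were pooled, is not stated in the labels. The deposited values were checked to be whole counts of unique molecular identifiers (UMIs) per gene and cell barcode, with a smallest barcode total of 500. The submitters' processing notes name Cell Ranger 3.0.0 and the genome build mm10. Each table held 31053 genes.

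Cells with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs were kept. Doublets were then called in each library with Scrublet as run by scanpy 1.11.5, at an expected rate of 6%, and left out. Counts were normalised to 10000 per cell and log-transformed, and 2000 variable genes were chosen within libraries. Genes of the interferon, inflammatory, immediate early, S phase, G2 and M phase and sex-linked lists, ribosomal protein genes and mitochondrial genes were left out of the clustering. The 3 libraries were clustered together on 30 principal components and 15 neighbours with leidenalg 0.10.2 at resolution 1, without correction between libraries. Clusters of at least 20 cells were named from 14 lists of marker genes fixed before the data were examined. Clusters with under 3 markers of their best class at 2-fold over other cells stayed unnamed, as did those with at least 3 markers of another class, or more of these than of their own, among their top 10 genes, and the cells of unnamed clusters count in the totals behind the shares. Names end in "like" because they rest on transcripts alone. The other tools were numpy 2.4.6, scipy 1.17.1, anndata 0.12.19 and matplotlib 3.10.9.

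For each population, UMIs were summed over the cells of a library and given per 1000000 UMIs of that population (CPM). Ratios were taken on the log2 scale after adding 10 CPM to both values, among genes with at least 100 UMIs over the pair of libraries compared. Folds without the added 10 CPM are given beside the levels. Levels carry exact Poisson 95% intervals and shares of cells carry exact Clopper-Pearson 95% intervals. These intervals cover counting error only. There were no replicate libraries, so no test across samples was made and all comparisons are values side by side. For 26 gene lists, holding 418 genes of which 1 was not in the tables, the median log2 ratio of the measured members is given. Its percentile among 10000 random lists of the same size, matched on expression in 20 bins, is a description of these libraries. Cell cycle shares are the percent of cells with at least 2 UMIs over a list after thinning to 2000 UMIs per cell. Cells with under 2000 UMIs were left out of the thinned values.

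The genes named were set by a rule written before the data were examined. For each of 3 comparisons and 3 populations (all kept cells, HSPC-like cells and neutrophil progenitor-like cells) it takes the 5 genes with the largest higher and the 5 with the largest lower log2 ratio. Ribosomal protein, mitochondrial, immunoglobulin, haemoglobin and predicted genes were left out of these top genes. The rule also takes up to 4 members with the largest absolute log2 ratio from each list described, and Kit, Ly6a, Cd34, Mpo, Elane, Cebpb, Csf3r, Gfi1 and Irf8 whatever their values. Of the genes that the rule takes, 1 is not reported here. Gene positions are those of GENCODE release M21 on GRCm38, which gave 1 gene for 30416 symbols. The release that the submitters counted against is not stated in the labels.

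The counting and ratio steps were tested on simulated data, Poisson counts drawn from the mean profile of HSPC-like cells of the challenged once and unchallenged libraries with known folds put in. All 98 genes given a 2-fold change and all 94 genes given a 4-fold change came out in the right direction. Of 100 unchanged simulated lists, 3 fell outside the 2.5 to 97.5 percentile range. Their members were drawn at random, so this does not cover genes that vary together or libraries that differ beyond counting error. In 4000 separate Poisson draws from fixed means, not taken from the libraries, the Poisson intervals held the true value in 96.7%. This checks the interval calculation only and not the spread between libraries.

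Alternatives set before any value was seen were a filter at 1000 UMIs and 500 genes, no filter on cells, keeping the Scrublet calls, Leiden resolution 2 and clustering on all variable genes. Others were median-of-ratios scaling, thinning to 2000 UMIs before summing, the mean of each cell's CPM, 1 CPM added in place of 10, and no minimum beyond 1 UMI. Cell cycle shares were repeated at 1 UMI and without thinning. After the data were seen, 3 alternatives were added, namely neutrophil progenitor-like clusters with at least 150 (tried first) or at least 100 cells of every library, and shares outside the immature and mature neutrophil-like classes. A list median at or beyond 0.2 on the log2 scale with a percentile outside 2.5 to 97.5 was treated as called when directions were compared, a rule also set after the medians were seen, as was the choice of the results whose values under the alternatives are given most fully.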

Results

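The libraries asked how Kit-enriched bone marrow cells differ after 1 or repeated challenge with Escherichia coli, in a series titled for the effect of infection on haematopoietic stem and progenitor cells (HSPCs) and neutrophil defence. The unchallenged library held 119646078 UMIs over 9684 barcodes, the challenged once library 135079828 over 9060 and the rechallenged library 95522747 over 8923. After filtering, 8796, 8356 and 8286 cells were kept, in that order. Their median depths were 10969, 13004 and 10247 UMIs, and their median mitochondrial shares were 2.07%, 2.58% and 4.1%. There were no replicates, so each difference below is between single libraries. The number of challenges and the labelled time, 24 or 48 h, differ together.

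Neutrophil lineage cells made up much of each library, and their stages were spread differently. Immature neutrophil-like cells, at the stage of specific granule genes, were 35.9% (34.9 to 36.9) of unchallenged cells, 11% (10.3 to 11.7) after 1 challenge and 17.9% (17.1 to 18.7) after repeated challenge. Neutrophil progenitor-like cells, at the stage of azurophil granule genes such as Elane and Mpo, were 13.9% (13.2 to 14.6), 21.4% (20.6 to 22.3) and 24.3% (23.4 to 25.2). HSPC-like cells were 7.64% (7.09 to 8.22), 12.5% (11.8 to 13.3) and 7.74% (7.17 to 8.33). The border between progenitor-like and immature cells rests on granule genes whose levels differed between libraries. Both classes together were 49.8% (48.7 to 50.8), 32.4% (31.4 to 33.4) and 42.2% (41.1 to 43.3).

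Several other classes also differed in share. Monocyte-like cells were 6.40%, 8.57% and 12% of the unchallenged, challenged once and rechallenged libraries, and dendritic cell-like cells 2.19%, 3.79% and 6.96%. Of the dendritic cell-like cells, 782 were in cluster 13, which had the lymphoid genes Dntt and Ly6d beside Siglech among its top 10 genes. Mature neutrophil-like cells were 4.42%, 5.29% and 8.22%. B lineage-like cells were 8.08%, 12.2% and 3.65%, and erythroid-like cells 8.45%, 11% and 4.83%. The B lineage-like cells were shallow, with median depths of 2654, 2303 and 1175 UMIs, and 283 of 302 rechallenged ones had under 2000 UMIs. Their shares may therefore move with the depth filter. Unnamed clusters held 603, 492 and 203 cells, of which 490, 425 and 141 were in cluster 9, whose best-scoring class was B lineage, so the B lineage shares depend on leaving it out. T, NK or innate lymphoid-like cells were 0.728%, 1.25% and 4.42%. Shares followed enrichment for Kit, so they do not give the make-up of whole marrow, and a lower share of immature neutrophils raises the share of every other class. Outside the immature and mature neutrophil-like classes, HSPC-like cells were 12.8%, 15% and 10.5%, which places the rechallenged library below the unchallenged one. On that base monocyte-like cells were 10.7%, 10.2% and 16.2% and erythroid-like cells 14.2%, 13.2% and 6.53%, so neither was higher after 1 challenge than unchallenged. B lineage-like cells were 13.5%, 14.5% and 4.93%, dendritic cell-like cells 3.68%, 4.53% and 9.43%, and T, NK or innate lymphoid-like cells 1.22%, 1.49% and 5.98%. The immature share after repeated challenge was 11.2% at the finer clustering and 10.3% without the cell filter.

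**Figure D1:**
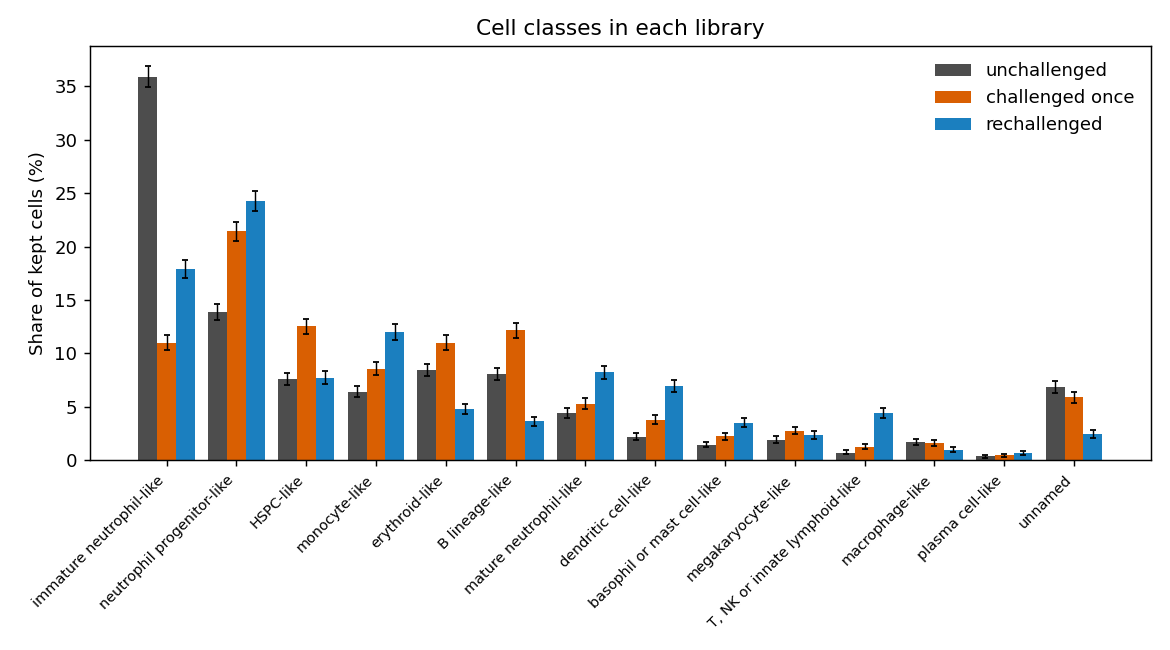
Share of kept cells (%) in each cell class, with 1 bar per library and exact 95% intervals that cover counting error only. Immature neutrophil-like cells were 35.9% of the unchallenged library and 11% of the challenged once library, while neutrophil progenitor-like cells were 13.9% and 21.4%.

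Some clusters came almost wholly from 1 library, which bears on every comparison within a class. Cluster 8, one of 4 neutrophil progenitor-like clusters, held 10 unchallenged, 14 challenged once and 1191 rechallenged cells. Monocyte-like cluster 10 held 4, 11 and 974, and immature neutrophil-like cluster 7 held 41, 54 and 1182. HSPC-like cells formed a single cluster with 672, 1047 and 641 cells. Scaling by the median of gene ratios in place of total UMIs moved the challenged once over unchallenged ratios by -0.19 over all cells, 0.03 in HSPC-like cells and -0.19 in neutrophil progenitor-like cells on the log2 scale. For rechallenged over unchallenged these shifts were 0.06, 0.20 and 0.01, and for rechallenged over challenged once 0.25, 0.18 and 0.20.

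In HSPC-like cells, the comparison of the challenged once with the unchallenged library asked what was different in stem and progenitor cells after 1 challenge. Cell cycle genes were higher as a group. All 26 S phase genes lay between 1.5-fold lower and 1.5-fold higher, with a median log2 ratio of 0.28 above all of the random lists (percentile 100), and examples were Rrm1 at 99.6 against 70.5 CPM and Gins2 at 64.2 against 44.1 CPM. Of 38 G2 and M phase genes, 2 were at least 1.5-fold higher and none lower (median 0.29, percentile 100), with Aurkb at 51.9 against 31.2 CPM and Birc5 at 192 against 122 CPM. Genes of oxidative phosphorylation were also higher, 3 of 22 by at least 1.5-fold and none lower (median 0.34), among them Sdhd at 128 against 65.1 CPM.

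The share of HSPC-like cells with S phase transcripts, at equal depth per cell, was 65.2% (61.5 to 68.8) unchallenged, 80.3% (77.8 to 82.7) after 1 challenge and 71.6% (67.9 to 75.1) after repeated challenge. Before thinning the median depths of these cells were 8821, 13905 and 9367 UMIs. In mature neutrophil-like cells, which have left the cycle, the same shares were 18.9%, 15.3% and 5.66% at median depths of 4266, 3124 and 3642 UMIs. These describe the deeper cells of that class, since 18 of 389, 148 of 442 and 257 of 681 cells had under 2000 UMIs and were left out. The G2 and M phase share was 84.3%, 84.6% and 75.6% in HSPC-like cells but 93.8%, 90.1% and 69.3% in mature neutrophil-like cells. It was thus higher in mature neutrophil-like cells of the unchallenged and challenged once libraries, and is not read as a share of cycling cells. No background share was measured. Without thinning, the S phase shares were 97%, 97.4% and 92.8%, near the ceiling in every library.

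Genes tied to stem cell identity were lower after 1 challenge in HSPC-like cells. Of 15 measured, 2 were at least 1.5-fold lower by the ratio with 10 CPM added and none higher (median -0.36, percentile 0), with Mycn at 16.7 against 41.3 CPM and Angpt1 at 50.9 against 97.6 CPM. Kit itself, the marker used for enrichment, was at 65.4 CPM (61.4 to 69.5) against 100 CPM (92.9 to 108). Ly6a, which encodes the stem cell marker Sca-1 and responds to interferon, was 1.56-fold higher (1.47 to 1.65), at 323 against 207 CPM. The interferon response list as a whole had a median of -0.07 over 29 genes, 1 at least 1.5-fold higher and 1 lower, and the median was 0.16 after thinning to equal depth. Of the 14 antigen presentation genes 3 were at least 1.5-fold higher and none lower, and the median of 0.13 lay within the range of most random lists (percentile 88.1). The members furthest apart were Cd74, the invariant chain, 3.35-fold higher (2.85 to 3.95) at 84.0 against 25.1 CPM, and H2-Eb1 at 18.0 against 5.84 CPM.

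Other genes higher in HSPC-like cells after 1 challenge were Ifitm1, an interferon-induced membrane protein gene, at 1967 against 811 CPM, Vldlr at 31.7 against 8.46 CPM, Cox7b at 263 against 130 CPM and Slc4a8 at 18.2 against 4.96 CPM. The largest differences were lower specific granule transcripts. All 12 measured members were at least 1.5-fold lower (median -2.42, percentile 0), with Camp, which encodes the antimicrobial peptide CRAMP, at 185 CPM (179 to 192) against 1816 CPM (1784 to 1848), Ngp at 138 against 1223 CPM, S100a9 at 636 against 4160 CPM, Ltf at 19.1 against 166 CPM and Lcn2 at 57.4 against 394 CPM. The same transcripts were lower in cells that should not make them: Camp was at 511 against 4313 CPM in B lineage-like cells and at 146 against 1412 CPM in erythroid-like cells.

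**Figure D2:**
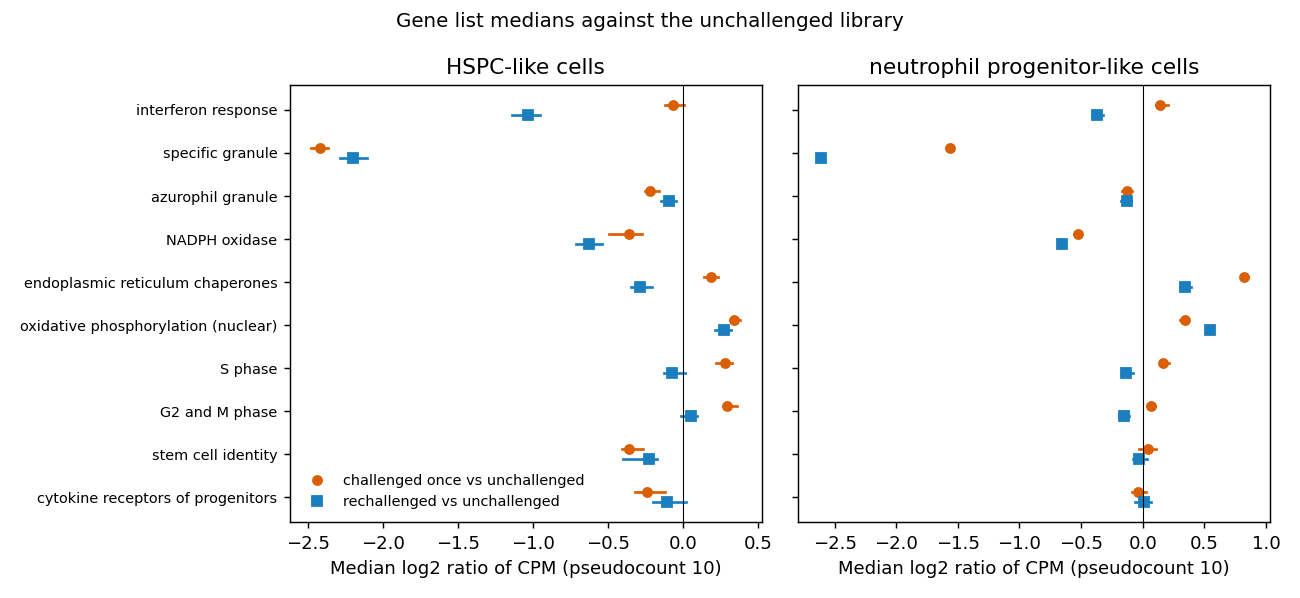
Median log2 ratio of CPM for 10 gene lists in HSPC-like and neutrophil progenitor-like cells, challenged once and rechallenged each against unchallenged, with bars for counting error from 200 Poisson draws. In HSPC-like cells the interferon response list lay at -0.07 after 1 challenge and -1.03 after repeated challenge, and the specific granule list at -2.42 and -2.20.

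After repeated challenge, HSPC-like cells had lower interferon response transcripts than unchallenged cells. Of 26 measured genes, 20 were at least 1.5-fold lower and none higher (median -1.03, percentile 0). Isg15, which encodes a ubiquitin-like modifier, was at 10.7 against 100 CPM, Irf7, a transcription factor of the interferon response, at 12.1 against 71.2 CPM, Ifit1 at 6.23 against 51.5 CPM and Rtp4 at 29.3 against 143 CPM. Ly6a was 1.94-fold lower (1.77 to 2.13), at 107 against 207 CPM. Oxidative phosphorylation genes were higher, 4 of 22 by at least 1.5-fold and none lower (median 0.27, and 0.46 with median-of-ratios scaling), with Ndufs6 at 208 against 113 CPM. S phase and G2 and M phase lists had medians of -0.07 and 0.05, and the S phase median was 0.09 with median-of-ratios scaling.

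The genes furthest above unchallenged in these cells were Nr4a1, an immediate early nuclear receptor gene, at 43.0 CPM (38.0 to 48.3) against 4.09 CPM (2.72 to 5.90), Hist1h2ap at 2026 against 636 CPM, Cox6a1 at 512 against 160 CPM, Tmem258 at 347 against 112 CPM and Cox7b at 384 against 130 CPM. Nr4a1 was also higher in dendritic cell-like cells, at 47.5 against 5.13 CPM, and in erythroid-like cells at low levels, at 4.05 against 0.506 CPM. Hist1h2ap was also higher in erythroid-like cells, at 3211 against 1070 CPM. All 31-mers (100%) in the last 300 bases of Hist1h2ap also occur in transcripts of other genes. Of 6 erythroid and megakaryocyte genes measured, 3 were at least 1.5-fold lower and 1 higher (median -0.69, percentile 0.01, and -0.25 with no minimum beyond 1 UMI), with Car1 at 4.67 against 27 CPM and Pf4 at 7.16 against 21.5 CPM. Specific granule transcripts were again lower, 12 of 12 by at least 1.5-fold (median -2.20), with Camp at 251 against 1816 CPM, Ngp at 144 against 1223 CPM, S100a9 at 657 against 4160 CPM, Chil3 at 26.5 against 216 CPM and Lcn2 at 59.3 against 394 CPM.

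The 2 challenged libraries also differed from each other in HSPC-like cells. Interferon response genes were lower in the rechallenged library, 17 of 28 by at least 1.5-fold and none higher (median -1.08, percentile 0), including Irf7 at 12.1 CPM (9.60 to 15.2) against 102 CPM (96.9 to 107), Isg15 at 10.7 against 70.5 CPM, Ifi27l2a at 71.9 against 288 CPM and Rtp4 at 29.3 against 130 CPM. With 1 CPM added in place of 10, the median was -1.62. Antigen presentation genes were lower, 7 of 14 and none higher (median -0.57, percentile 0.29), with Cd74 at 24.1 against 84.0 CPM, H2-D1 at 457 against 932 CPM and B2m at 1748 against 2924 CPM, and the class I-like gene H2-T23 was at 43.0 against 164 CPM. Immediate early and stress genes went both ways, 5 of 14 at least 1.5-fold higher and 4 lower (median 0.26, and 0.55 at Leiden resolution 2): Nr4a1 was at 43.0 against 4.59 CPM, Egr1 at 65.9 against 12.6 CPM and Fos at 291 against 132 CPM, whereas the chaperone gene Hsp90aa1 was at 755 against 1477 CPM. The chemokine genes Ccl3, at 75.0 against 14.2 CPM, and Ccl4, at 206 against 53.0 CPM, were higher too, as was Kit, 1.96-fold (1.78 to 2.15) at 128 against 65.4 CPM. Hist1h2ap was at 2026 against 249 CPM. Some of these differences were not particular to HSPC-like cells. Egr1 was also higher in the rechallenged library in erythroid-like cells, at 53.8 against 25.5 CPM, and in megakaryocyte-like cells, at 104.9 against 30.4 CPM. Across the unchallenged, challenged once and rechallenged libraries, the progenitor marker Cd34 was at 352, 273 and 238 CPM and the G-CSF receptor gene Csf3r at 35, 32.8 and 39.1 CPM in HSPC-like cells.

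In neutrophil progenitor-like cells, genes for chaperones of the endoplasmic reticulum, which fold secreted and granule proteins, were higher after 1 challenge. Of 16 measured, 12 were at least 1.5-fold higher and none lower (median 0.82, percentile 100), with Hspa5, which encodes BiP, at 1106 against 439 CPM, Sdf2l1 at 1129 against 477 CPM, Creld2 at 215 against 69.4 CPM and Hsp90b1 at 727 against 325 CPM. Of 12 immediate early and stress genes, 4 were at least 1.5-fold higher and none lower, with Hspa1b at 34.9 against 4.09 CPM and Hsp90aa1 at 1722 against 736 CPM (median 0.34, and 0.14 in the single cluster with at least 150 cells of every library). In that cluster the endoplasmic reticulum chaperone median was 0.36, and it was 0.56 in the clusters with at least 100 cells of every library. The single cluster was cluster 5, with 163 unchallenged, 531 challenged once and 686 rechallenged cells. Chaperone genes were not left out of the clustering, and Calr and Hspa5 were among its top 10 genes. Part of the class-wide difference may therefore reflect more cells in that cluster.

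Saa3, which encodes an acute phase serum amyloid protein, was at 94.4 CPM (91.6 to 97.2) after 1 challenge against 0.953 CPM (0.590 to 1.46) in unchallenged neutrophil progenitor-like cells. Ifitm1, at 372 against 44.7 CPM, Ifitm3, at 780 against 207 CPM, and Chchd10, at 148 against 38.5 CPM, were also higher. The interferon response list had a median of 0.14 over 26 genes, 2 at least 1.5-fold higher and none lower, and Bst2 was at 243 against 112 CPM. Irf8, a transcription factor of monocyte and dendritic cell fate, was 1.89-fold higher (1.66 to 2.16), at 24.1 against 12.7 CPM, but its log2 ratio of 0.58 was -0.14 with the filter at 1000 UMIs and 500 genes. Cebpb, which drives granulocyte output in emergencies, was at 243 against 244 CPM. In the unchallenged, challenged once and rechallenged order, neutrophil progenitor-like cells had Cd34 at 28.6, 33.9 and 26.5 CPM and Csf3r at 45.1, 40.3 and 50.3 CPM.

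Granule genes of later stages were lower in neutrophil progenitor-like cells after 1 challenge. Of 13 specific granule genes, 12 were at least 1.5-fold lower and none higher (median -1.56), with Ltf at 91.8 against 525 CPM, Camp at 3388 against 17720 CPM, Lyz2 at 518 against 2639 CPM and Ngp at 2155 against 9628 CPM. Fcnb, which encodes ficolin B, was at 206 against 1165 CPM. The make-up of the class differed too: cluster 15, with Fcnb and Cebpe among its top 10 genes, held 487 unchallenged, 235 challenged once and 26 rechallenged cells. These lower levels therefore do not compare the same mix of cells. Camp was also lower in erythroid-like cells, at 146 against 1412 CPM. The part of free RNA from other cells was not tested in this class. NADPH oxidase genes, whose products make the oxidative burst, were lower in 3 of 7 and higher in none (median -0.53), with Cybb at 82.2 against 184 CPM. Among azurophil granule genes Elane was 1.62-fold lower (1.61 to 1.63), at 7122 against 11550 CPM, and Mpo was at 3886 against 4855 CPM, while the list had 1 of 9 at least 1.5-fold higher and 2 lower (median -0.13). These medians moved with the clusters used. In clusters with at least 100 cells of every library the specific granule median was -0.67 and the NADPH oxidase median -0.16, and in the single cluster with at least 150 they were -1.89 and -0.08.

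After repeated challenge, neutrophil progenitor-like cells again had more Ifitm1, at 267 against 44.7 CPM, and Saa3, at 36.7 CPM (34.6 to 38.9) against 0.953 CPM, than unchallenged cells. Jund, an AP-1 transcription factor gene, was at 113 against 20.8 CPM, Polr2l at 287 against 84.5 CPM and Alyref at 230 against 70.1 CPM. Jund was higher in other classes too, at 165.4 against 35.9 CPM in monocyte-like and 351 against 143.6 CPM in erythroid-like cells. Polr2l was higher in rechallenged than in challenged once erythroid-like cells, at 301.4 against 100.3 CPM, and megakaryocyte-like cells, at 200.7 against 67.6 CPM. Gfi1, which encodes a repressor needed for granulocyte development, was 1.65-fold higher (1.52 to 1.79), at 66.1 against 40.1 CPM, but its log2 ratio of 0.60 was 0.06 in clusters with at least 100 cells of every library. Oxidative phosphorylation genes were higher, 8 of 22 by at least 1.5-fold and none lower (median 0.54, percentile 99.99), with Uqcr11 at 1201 against 598 CPM. Endoplasmic reticulum chaperones were higher in 5 of 16 and lower in none (median 0.34), with Hsp90b1 at 858 against 325 CPM, but the median was -0.03 in clusters with at least 100 cells of every library and 0.09 in the cluster with at least 150.

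Interferon response genes were lower after repeated challenge in neutrophil progenitor-like cells too, 6 of 22 by at least 1.5-fold and none higher (median -0.37, percentile 0), with Isg15 at 1.70 against 22.2 CPM and Rtp4 at 1.13 against 15.2 CPM. With 1 CPM added the median was -0.57, and with no minimum beyond 1 UMI it was -0.23. Specific granule genes were lower in 12 of 13 and higher in none (median -2.61), with Ngp 19.8-fold lower (19.4 to 20.1) at 488 against 9628 CPM, Ltf at 30.9 against 525 CPM, Lyz2 at 203 against 2639 CPM, Chil3 at 113 against 1483 CPM and Camp at 1849 against 17720 CPM. That median was -1.65 with the filter at 1000 UMIs and 500 genes. Cluster 15 of this class, with Fcnb among its top 10 genes, held 487 unchallenged and 26 rechallenged cells. Erythroid-like and B lineage-like cells of the rechallenged library had Ngp at 318.4 and 386.9 CPM, against 958.8 and 3020 CPM unchallenged. They had Ltf at 60.8 and 107.2 CPM, above the progenitor-like level, but Camp at 562.5 and 630.1 CPM, below it. The part of free RNA from other cells was not tested in neutrophil progenitor-like cells. NADPH oxidase genes were lower in 5 of 7 and higher in none (median -0.65, and -0.08 in the cluster with at least 150 cells of every library), with Ncf4 at 81.4 against 233 CPM.

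Against the challenged once library, neutrophil progenitor-like cells of the rechallenged library had 12 of 26 interferon response genes at least 1.5-fold lower and none higher (median -0.52, and -1.09 with 1 CPM added), with Bst2 at 84.7 against 243 CPM and Rtp4 at 1.13 CPM (0.784 to 1.56) against 24.7 CPM (23.2 to 26.1). Ifitm3 was at 234 against 780 CPM and Hspa1b at 3.50 against 34.9 CPM. Endoplasmic reticulum chaperones were lower in 4 of 16 and higher in none (median -0.35, and -0.16 with median-of-ratios scaling), with Creld2 at 107 against 215 CPM. Higher were Hist1h2ap, at 1240 against 110 CPM, Jund, at 113 against 22.2 CPM, Hist1h2br, at 24.0 against 2.71 CPM, and Gstp1, at 50.5 against 13.1 CPM. Jund was also higher in monocyte-like cells, at 165.4 against 32.5 CPM, and in erythroid-like cells, at 351 against 177 CPM. So was Gstp1, at 68 against 18.2 CPM and 128.2 against 35.9 CPM in these classes, but it differed less in B lineage-like cells, at 28.8 against 22 CPM. Hist1h2ap was at 1484 against 130 CPM in monocyte-like and 3211 against 281 CPM in erythroid-like cells. These 3 differences were thus not particular to neutrophil progenitor-like cells. Ngp was at 488 against 2155 CPM and Chil3 at 113 against 495 CPM. The specific granule list was lower in 7 of 13 and higher in 1 (median -0.87), but its median was 0.10 in the cluster with at least 150 cells of every library.

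Over all kept cells, ratios mix levels within cells with the shares of cell classes. After 1 challenge, Wfdc17 was at 215 CPM (213 to 218) against 21.8 CPM (21 to 22.7) and Saa3 at 49.9 against 0.661 CPM, and the secretory pathway genes Sdf2l1, at 603 against 198 CPM, and Fkbp11, at 69.6 against 16.3 CPM, were higher, as was Ifitm1 at 627 against 149 CPM. Endoplasmic reticulum chaperones were at least 1.5-fold higher in 11 of 16 and lower in none (median 0.92). Interferon response genes were higher in 5 of 30 and lower in none (median 0.32, 0.21 with median-of-ratios scaling and 0.60 as the mean of each cell's CPM). The marker of granulocytes Ly6g was at 28.4 against 209 CPM, and specific granule genes were lower in 13 of 13 (median -1.84), with Camp at 4973 against 25280 CPM, Ngp at 3935 against 18580 CPM, Lyz2 at 1065 against 4928 CPM and Ltf at 542 against 2487 CPM.

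After repeated challenge, all kept cells had higher levels of Wfdc17, at 324 against 21.8 CPM, Stfa2l1, at 48.5 against 1.01 CPM, the chemokine genes Ccl5, at 120 against 16.4 CPM, and Ccl6, at 43.1 against 4.24 CPM, and Prg2, at 62.0 against 9.09 CPM. Inflammatory genes were higher in 8 of 22 and lower in 1 (median 0.36, and 0.81 with 1 CPM added), with Il1b at 22.5 against 0.724 CPM and Cxcl2 at 24.0 against 1.64 CPM. Interferon response genes were lower in 13 of 29 and higher in none (median -0.39, and -1.07 with 1 CPM added). Erythroid and megakaryocyte genes were lower in 10 of 19 and higher in none (median -0.96, and -0.35 after thinning), with Klf1 at 13.2 against 80.9 CPM and Car2 at 122 against 569 CPM. The B lineage genes Vpreb1, at 28.1 against 162 CPM, Cd79a, at 20.5 against 122 CPM, and Mzb1, at 12.4 against 82.0 CPM, were lower beside the lower B lineage share given above. Chil3 was at 676 against 2928 CPM.

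Between the challenged libraries, all kept cells of the rechallenged library had higher Hist1h2ap, at 1690 against 184 CPM, S100a6, at 785 against 210 CPM, and the stefin genes Stfa2l1, at 48.5 against 5.35 CPM, and Stfa1, at 55.1 against 7.22 CPM. They had lower Irf7, at 4.48 CPM (4.06 to 4.94) against 46.3 CPM (45.1 to 47.5), Rtp4, at 8.71 against 58.7 CPM, Vpreb1, at 28.1 against 144 CPM, Vpreb3, at 47.3 against 213 CPM, and Cd79a, at 20.5 against 106 CPM. Interferon response genes were lower in 17 of 30 and higher in none (median -0.76, and -1.62 with 1 CPM added). Specific granule genes were higher in 5 of 13 and lower in none (median 0.54), but the median was 0.11 after thinning and 0.07 as the mean of each cell's CPM.

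**Figure D3:**
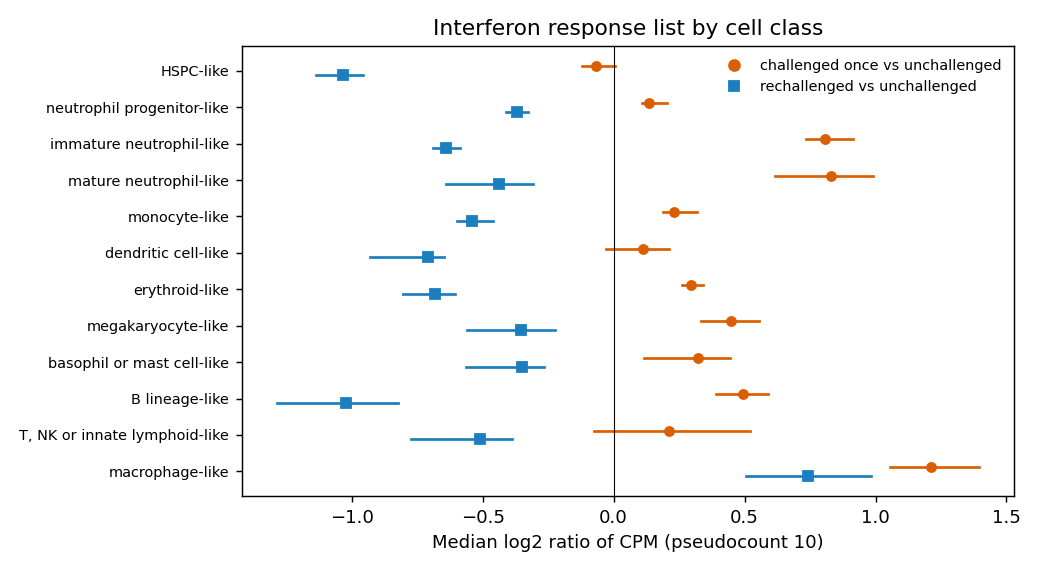
Median log2 ratio of the interferon response list in each cell class, challenged once and rechallenged each against unchallenged, with bars for counting error from 200 Poisson draws. The rechallenged medians lay below 0 in 11 of the 12 classes and the macrophage-like class, with 3 measured genes, lay at 0.74.

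The genes that recur above sit at known places on GRCm38. Isg15 lies on chromosome 4 from 156199424 to 156200818 on the minus strand, Irf7 on chromosome 7 from 141262706 to 141266481 on the minus strand and Ly6a on chromosome 15 from 74994877 to 74998031 on the minus strand. Saa3 lies on chromosome 7 from 46711998 to 46715700 on the minus strand, Ifitm1 on chromosome 7 from 140967221 to 140969825 on the plus strand, Camp on chromosome 9 from 109847379 to 109849617 on the minus strand and Kit on chromosome 5 from 75574916 to 75656722 on the plus strand. All 7 are annotated as protein coding.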

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

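Of the tests of the interferon response list here, those of scaling and of depth were chosen only after the result was seen. Over all cells the list's median log2 ratio against the unchallenged library was 0.32 after 1 challenge and -0.39 after repeated challenge, a difference of 0.71. It stands out because the challenged libraries lay on opposite sides of the unchallenged one over all cells, although the first value was 0.21 with median-of-ratios scaling and in HSPC-like cells the medians were -0.07 and -1.03, the former being 0.16 after thinning. The difference was not tested, since each group has 1 library and both ratios share the unchallenged library.

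The list was lower in the rechallenged library than in the challenged once library, and technical explanations were weighed in HSPC-like cells. Scaling by total UMIs is argued against as the whole cause, since the median stayed at -1 with median-of-ratios scaling, and so is depth per cell, since it stayed at -1.26 with cells thinned to 2000 UMIs. Free RNA in the challenged once library could contribute and stays open: the members' UMIs per cell in HSPC-like cells were 1.26 times those in erythroid-like cells, within the range of 0.5 to 2 that free RNA would need, although genes that all cells express would give the same value. A biological difference after repeated challenge, or between 24 and 48 h, also stays open and untested, because each of these differs along with the single library.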

How the results depend on the processing

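All alternatives planned before the data were examined were run, and those named below as clusters with at least 100 or 150 cells, or as outside neutrophil classes, were chosen after seeing the data. No paired analysis was possible because the labels give no link between animals of different libraries. Shares of HSPC-like, neutrophil progenitor-like and immature neutrophil-like cells are given in the order unchallenged, challenged once, rechallenged, or with the library named. The cause of each move was not tested. At Leiden resolution 2, HSPC-like cells were 6.53%, 9.93% and 4.73%, progenitor-like cells 20% after 1 and 23.3% after repeated challenge, and immature cells 11.2% after repeated challenge. With at least 1000 UMIs and 500 genes, HSPC-like cells were 6.86%, 10.7% and 6.5%, progenitor-like cells 10.3%, 15.6% and 23%, and immature cells 39.1% unchallenged and 12.2% after 1 challenge. With no filter on cells, HSPC-like cells were 9.94% after repeated challenge, progenitor-like cells 11.8%, 19.4% and 28.9%, and immature cells 33.8%, 9.92% and 10.3%. With Scrublet calls kept, HSPC-like cells were 6.69% unchallenged and 11.3% after 1 challenge, and progenitor-like cells 23.1% after repeated challenge. With all variable genes used for clustering, HSPC-like cells were 8.36% after repeated challenge, progenitor-like cells 12.2% unchallenged and 30.6% after repeated challenge, and immature cells 37% and 11.7%. Outside the immature and mature neutrophil classes, HSPC-like cells were 12.8%, 15% and 10.5% and progenitor-like cells 23.3%, 25.6% and 32.9%. The share of HSPC-like cells with S phase transcripts was 87.3%, 92.3% and 88.4% at 1 UMI and 97%, 97.4% and 92.8% not thinned, and for G2 and M phase 94.5%, 94.4% and 91% at 1 UMI and 99.6%, 99% and 95.6% not thinned.

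Median log2 ratios of the interferon response list in HSPC-like cells, challenged once over unchallenged, were 0.16 with cells thinned to 2000 UMIs and 0.13 as the mean of each cell's CPM, against -0.07. Rechallenged over unchallenged they were -1.15 thinned, -1.49 with 1 CPM added, -0.92 with no minimum beyond 1 UMI and -0.91 with at least 1000 UMIs and 500 genes. Rechallenged over challenged once they were -1.26 thinned, -1.27 as the mean of each cell's CPM and -1.62 with 1 CPM added.

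In neutrophil progenitor-like cells, challenged once over unchallenged, the interferon median was 0.06 with median-of-ratios size factors, 0.28 as the mean of each cell's CPM, 0.32 with 1 CPM added, 0.10 with no minimum, 0.10 at 1000 UMIs and 500 genes, and 0.03 in clusters with 100 and 0.03 with 150 cells of every library. The specific granule median was -1.75 with median-of-ratios size factors, -1.38 thinned, -1.42 as the mean of each cell's CPM, -1.59 with 1 CPM added, -0.86 at 1000 UMIs and 500 genes, -1.33 at Leiden resolution 2, -0.67 in clusters with 100 cells and -1.89 with 150. The endoplasmic reticulum chaperone median was 0.64 with median-of-ratios size factors, 0.87 with 1 CPM added, 0.79 at 1000 UMIs and 500 genes, 0.56 in clusters with 100 cells and 0.36 with 150.

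In the same cells, rechallenged over unchallenged, the interferon median was -0.57 with 1 CPM added, -0.23 with no minimum, -0.51 at 1000 UMIs and 500 genes, -0.42 at Leiden resolution 2, -0.46 in clusters with 100 cells and -0.54 with 150. The specific granule median was -2.46 thinned, -2.48 as the mean of each cell's CPM, -2.80 with 1 CPM added, -1.65 at 1000 UMIs and 500 genes, -2.56 with Scrublet calls kept, -2.44 at Leiden resolution 2, -2.10 in clusters with 100 cells and -1.92 with 150. The chaperone median was 0.20 at 1000 UMIs and 500 genes, 0.28 at Leiden resolution 2, 0.09 in clusters with 150 cells and turned to -0.03 with 100.

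Other values that turned direction, again with the cause not tested, were the haemoglobin list over all cells, challenged once over unchallenged, at 0.32 thinned and 0.25 as the mean of each cell's CPM, against -0.31. The gelatinase granule list in that comparison was 0.06 as the mean of each cell's CPM, against -0.23. Rechallenged over challenged once in progenitor-like cells, Irf8 was 0.07 at 1000 UMIs and 500 genes, against -0.64, and the specific granule list was 0.10 in the cluster with 150 cells, against -0.87. Of 234 list medians, 77 stayed within counting error with median-of-ratios scaling, 106 thinned and 216 with Scrublet calls kept. Of 171 gene ratios, 77, 72 and 146 did. The phagocytic receptor list of HSPC-like cells, rechallenged over challenged once, gave no value at Leiden resolution 2. Every comparison is limited by 1 library per group.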

Other observations

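Of the tests in this part, the test of free RNA for granule transcripts was chosen only after the result was seen, as were the comparison with other genes and the count of genes sharing nothing in the test of shared reads. The classes and genes in this paragraph and the next were chosen after their values were seen. Mature neutrophil-like cells had higher inflammatory transcripts in both challenged libraries. Against unchallenged, 10 of 12 inflammatory genes were at least 1.5-fold higher after 1 challenge and none lower (median log2 ratio 0.95), and 9 of 12 were higher and 1 lower after repeated challenge (median 1.04). Il1b, the gene of interleukin 1 beta, was at 691 and 881 CPM against 11.6 CPM, and the neutrophil chemokine gene Cxcl2 was at 1029 and 883 CPM against 34.2 CPM. These genes took no part in the clustering, but Il1b was among the markers that named this class, so its level is not independent of the class. Il1b and Cxcl2 were also among the top 10 genes of cluster 16. That cluster held 283 challenged once, 443 rechallenged and 3 unchallenged cells of the class.

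Basophil or mast cell-like cells of the rechallenged library had 7 of 9 inflammatory genes at least 1.5-fold higher than unchallenged and none lower (median 1.31), with Tnfaip3, a brake on NF-kB signalling, at 152 against 22.2 CPM and Ccl3 at 279 against 64.7 CPM. In the same class the eosinophil granule genes Prg2, at 1901 against 247 CPM, and Epx, at 147 against 21.6 CPM, were higher. Cluster 24, with 113, 67 and 60 cells of the unchallenged, challenged once and rechallenged libraries, scored best for eosinophils and had Prg2 and Epx among its leading genes, but stayed unnamed because 3 markers of another class were among its top 10 genes, against 5 of its own. Monocyte-like cells had Saa3 at 46.3 CPM after 1 challenge against 1.71 CPM. The interferon response median in immature neutrophil-like cells was 0.81 after 1 challenge, with 14 of 21 genes at least 1.5-fold higher and none lower, and -0.64 after repeated challenge, with 10 of 20 lower and none higher. Of these cells, cluster 7 held 41 unchallenged and 1182 rechallenged ones and cluster 0 held 1926 and 38, so the last value compares largely different clusters.

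Specific granule transcripts were lower in HSPC-like cells of both challenged libraries, at a median of 30 and 23 UMIs per cell against 122 in the unchallenged library. Doublets are argued against as the cause, since the 10% of unchallenged HSPC-like cells with most of these UMIs held 21% of them, where joined cells would have held over 50%. Free RNA from neutrophils could account for much of the pattern and cannot be told apart from transcripts of the cells themselves: the members' UMIs per cell in HSPC-like cells were 0.49 times those in erythroid-like cells of the unchallenged library, just under the lower bound of 0.5 set for free RNA and far from the value above 2 that would have excluded it. That a value under 0.5 leaves the question open was settled after it was seen; across the members the ratio ran from 0.434 to 0.781, and erythroid-like and B lineage-like cells carried a median of 229 and 82 UMIs of the list. A lower level in the progenitors themselves stays open and untested.

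In the rechallenged library 8 genes were at least 1.5-fold higher than in the challenged once library, by the ratio with 10 CPM added, in each of 8 classes (HSPC, neutrophil progenitor, immature neutrophil, monocyte, dendritic cell, erythroid, basophil or mast cell, and T, NK or innate lymphoid). This was out of 2157 genes measured in all of them, and Hist1h2ap, Gm10076, Gm8186, Cops9, Smim27, Snrpg and Lockd were among them. Short transcripts as such are argued against, although 7 of the 8 genes were among the 10% of genes with the shortest transcripts. In HSPC-like cells that 10% lay -0.04 from the other genes on the log2 scale. The test of scaling by total UMIs could not decide. In HSPC-like cells the set's median was 1.24 with that scaling and 1.41 with median-of-ratios scaling, which moved ratios by 0.18. The genes were chosen as at least 1.5-fold higher in these cells, so a shift of this size could not have undone the result. Reads shared with other genes may account for part of the set: 62.5% of the genes, 5 of 8, shared at least 10% of the 31-mers of their last 300 bases with transcripts of other genes, against 6.38% of 298 other genes. For the other 3 genes, Cops9, Smim27 and Snrpg, no such 31-mer was shared, so this search gave no sign of shared reads for them. It covered only the last 300 bases and annotated transcripts, and the release that the submitters counted against is not known. No biological explanation was tested. A difference in handling or annotation of either challenged library stays open, although each table held 31053 genes. The set was defined by the ratio of the challenged libraries, which does not show which of them departed. Across the unchallenged, challenged once and rechallenged libraries, Hist1h2ap was at 1070, 281 and 3211 CPM in erythroid-like cells. In monocyte-like cells it was at 550.6, 130 and 1484 CPM.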
